A study of Angelica pubescens with 12 samples.

How the data were processed

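RNA from roots of Angelica pubescens plants aged 2 years was sequenced as 12 libraries, 3 from each of 4 producing areas, Chongqing, Gansu, Hubei and Shanxi. Area and replicate number were taken from the sample titles. The deposited estimated counts are values per unigene that need not be whole and were not scaled to a common total, as the deposited values show. The deposited FPKM values are scaled by the authors for unigene length and library total, as the deposited values show, and dividing them by the deposited counts gave 1 length per unigene up to a constant of each library. A de novo assembly underlies both kinds of value, per the unigene identifiers that the authors deposited. FastQC, Trimmomatic, Bowtie2, featureCounts, RSEM and DESeq2 are named in the submitters' processing notes, and their versions, roles and order, how libraries were pooled for the assembly, and how reads shared by similar unigenes were divided are not given in the sources used here. Unigenes of 1 gene, of close paralogs or of alleles can therefore share or split reads, which makes the value of a single unigene uncertain as a measure of its gene.

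Estimated counts were rounded to whole numbers for the tests. The 12 libraries held 19920136 to 23319714 counts, so that 3 counts, taken as the floor for a library or area at 0, correspond to about the same level in each library. Of 67432 unigenes, 28596 had a Swiss-Prot description, 11052 others an NR description, and 27528 had no description. The count test was the quasi-likelihood test of edgeR (version 4.0.16, glmQLFit and glmQLFTest) under R 4.3.3, with TMM normalization and the filter of filterByExpr by area, which left 60756 unigenes. All 12 libraries entered 1 fit with 8 residual degrees of freedom, without covariates. An overall test asked whether any area differed, and 6 further tests compared the areas in pairs. P-values were adjusted by the Benjamini-Hochberg method over all tested unigenes, and unigenes with an adjusted p under 0.05 were called. TMM factors ran from 0.941 to 1.05, and the biological coefficient of variation was 0.251. Values given as CPM are counts scaled to a common library size by edgeR's cpm function with TMM factors. Fold changes are log2, and their standard error (SE) is the absolute log2 fold change divided by the square root of the test's F value. Where an area had few counts this error can be too small, since leaving out 1 library can move the fold change by more. Where the value of a named unigene moved by over 1.5 times without 1 library, the value without it is given too, as a ratio with an exact binomial 95% counting interval where 1 to 3 counts were left in the lower area. A 95% interval or a floor covers counting error only. Distances between libraries were 1 minus Spearman's correlation of log2 CPM with an offset of 0.5, and the mean distance between areas minus that within areas was tested against all 15400 partitions of the libraries into 4 groups of 3. A unigene detected in 1 area only had 10 or more counts in each library of that area and 0 counts in the other 9.

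Before the data were examined, 34 gene lists were fixed for secondary metabolism, stress, hormones, nutrition, growth, tissue types and viruses, together with 14 pathway enzymes, the tests, the rule for named unigenes and most of the other settings tried. A unigene belonged to a list when its description, taken from Swiss-Prot, else NR, else KEGG, else other sources, matched the list's terms. Lists with 5 or more tested members were tested with camera of limma (version 3.58.1) at a preset correlation of 0.01, adjusted over all 198 combinations of list and pair, and again with an estimated correlation and with fry. Fitted fold changes of members with 0 counts in an area depend on the prior count, so medians of some lists are given also with these members at their bound. The rule named, for each pair, the 4 highest and 4 lowest log2 fold changes among called unigenes with an informative description, a mean log2 CPM of 3 or more, no overlap between the libraries of the areas and more than 3 counts in each area, with 1 unigene per description. It also named the 2 called members with the smallest p in the direction of each called list, the most abundant tested unigene of each pathway enzyme, and the 6 unigenes with the smallest p in the overall test that had a description and a mean log2 CPM of 3 or more. This gave 137 unigenes, of which the report gives those that lead each comparison. Of the 14 enzymes, 13 had a tested unigene. The result for 1 of them is not reported here.

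Settings tried for comparison, chosen in advance, were DESeq2 (version 1.42.0), RLE normalization, no count filter, a filter of 50 counts in 3 libraries, a minimum of 2-fold, limma with a trend on log2(FPKM + 1) and log2(FPKM + 0.1) for unigenes of at least 1 FPKM, the replicate number as a block, fits with only the areas compared, and the removal of each library in turn. The distance was also computed as 1 minus Pearson's correlation of log2(FPKM + 1), and the count of unigenes of 1 area with a minimum of 50 counts or with up to 2 counts elsewhere. Added after the data were seen were counts summed per best NR protein (24806 of 26255 proteins tested, coefficient of variation 0.0943), a covariate for libraries with 10 or more paramyxovirus counts, fits without fungal and viral unigenes, fits with only the unigenes that had counts in every library, and the count of unigenes of 1 area without each library. The test of replicates for counting noise used a chi-square over unigenes with 20 or more counts. Tables were prepared with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and in R with data.table (version 1.17.8).

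The fit was tested on simulated counts for Chongqing against Hubei, with 57351 unigenes tested, 50 of them changed for each fold size. It recovered 24% of changes of 1.5-fold, 52% of 2-fold, 70% of 4-fold and 96% of 8-fold, with 4 false calls. With so few changed unigenes the adjusted threshold is stricter than in the real pair, where 49.6% were called. The recovered shares therefore do not measure the sensitivity of the real tests. A pair simulated without change gave 0 calls, a raised list was called, and 0 of 180 random lists were. Genome positions were not used, since the assembly has no genome, and sequences were not analysed.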

Results

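Roots of Angelica pubescens, the source of the drug Angelicae Pubescentis Radix, came from 4 Chinese producing areas, Chongqing, Gansu, Hubei and Shanxi. RNA of roots aged 2 years was sequenced in 12 libraries, 3 per area, and the question was how gene expression differs between areas with different environments. No genome was used, and each unigene is a sequence of a de novo assembly, named by its identifier and its best protein match. Of the 67432 unigenes, 85.6% to 89% had counts in a given library. The 10 most abundant unigenes took 7.32% to 7.74% of the counts of the Shanxi libraries and 4.76% to 5.58% of the others. Every pair of replicates of an area differed by more than counting noise, with chi-square values of 4.58 to 9.52 per degree of freedom over the 12 pairs. The labels do not say that the replicates are separate plants, so p-values measure only the spread between these samples, which may be technical.

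The roots of the 4 areas had clearly different transcriptomes. A basic form of pathogenesis-related protein 1 (TRINITY_DN29604_c0_g1_i1_2), a secreted protein of defense, stood at 817 ± 44.3 normalised counts (CPM, mean ± SD, n = 3) in Chongqing and 332 ± 18.5 in Gansu, but at 2.39 ± 0.394 in Hubei and 1.78 ± 0.262 in Shanxi. A dehydrin (TRINITY_DN21801_c0_g5_i1_1), a protein that accumulates in drying or chilled tissue, stood at 2796 ± 107 CPM in Chongqing and 3255 ± 198 in Gansu against 14.2 ± 0.635 in Hubei and 169 ± 16.3 in Shanxi. A late embryogenesis abundant protein (TRINITY_DN17327_c0_g1_i4_2) was likewise higher in Chongqing and Gansu, with 76.7 ± 1.59 CPM in Chongqing, 172 ± 14.9 in Gansu, 0.312 ± 0.0402 in Hubei and 0.319 ± 0.057 in Shanxi. Single areas stood out for other unigenes. Glycine-rich protein HC1 (TRINITY_DN20691_c0_g1_i3_1) reached 2878 ± 107 CPM in Chongqing against 53.7 to 393 elsewhere. Chalcone synthase 2 (TRINITY_DN22168_c2_g1_i3_4), the entry enzyme of flavonoid synthesis, reached 623 ± 32.1 CPM in Gansu against 0.989 to 7.54 elsewhere, and serine carboxypeptidase-like 18 (TRINITY_DN25052_c0_g1_i12_3) 240 ± 9.87 CPM in Hubei against 0.602 to 13.2. Among unigenes with a description and a mean log2 CPM of 3 or more, these 6 had the smallest p in the test of any difference. Their edgeR adjusted p lay between 2.6e-14 and 3.9e-14.

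Of 60756 unigenes tested, edgeR called 42773 (70.4%) as different between at least 2 of the areas. Spearman correlations of log2 CPM were 0.942 to 0.96 within areas and 0.711 to 0.769 between areas. The mean distance, 1 minus that correlation, was 0.259 between areas and 0.0453 within them, a difference of 0.214, or 0.118 with counts summed over the unigenes that share their best protein, a unit of counting chosen after the data were seen. An exact permutation over all 15400 partitions of the 12 libraries gave no other value as large (one-sided p = 6.5e-05, the smallest that these partitions can give), and the highest other value was 0.139. Chongqing and Gansu were the closest pair of areas (mean correlation 0.766) and those of Gansu and Hubei (0.719) and of Chongqing and Shanxi (0.723) were the lowest. Calls were fewest for Chongqing and Gansu, 23384, in this and every other setting. They ran up to 30698 for Gansu and Hubei, but Chongqing and Hubei had the most calls in some other settings, such as fits with only the areas compared (29293 against 27774) and summed proteins (17380 against 17313). With summed counts 22108 of 24806 proteins differed between areas. The log2 fold change of these sums is given as the summed value beside a named unigene where it departs clearly from the unigene's own. The largest rises and falls named for each pair are those among annotated unigenes with a mean log2 CPM of 3 or more and more than 3 counts in each area compared, and unigenes with fewer counts in an area can have larger folds.

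**Figure D1:**
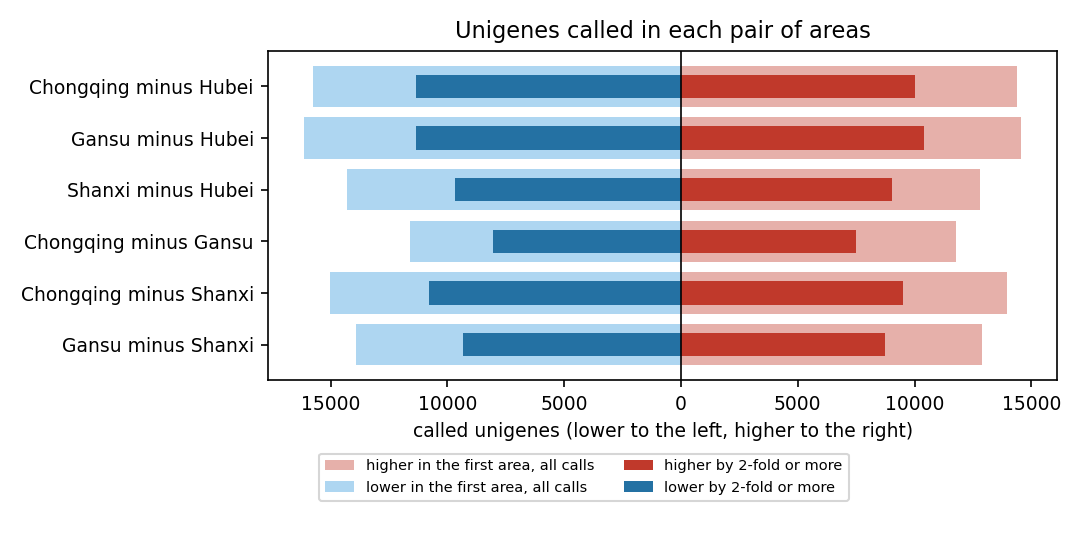
Horizontal bars give the number of unigenes called by edgeR in each pair of areas, to the right where the first-named area was higher and to the left where it was lower. Wide pale bars hold all calls and narrow dark bars those of 2-fold or more, and the fewest calls, 23384, are those between Chongqing and Gansu.

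The enzymes of phenylpropanoid and coumarin synthesis, fixed as a group because coumarins are the characteristic compounds of this root, were lowest in Chongqing for most steps. Phenylalanine ammonia-lyase 3 (PAL, TRINITY_DN23454_c1_g2_i2_3), the first step of the phenylpropanoid pathway, stood at 25.1 ± 2.05 CPM in Chongqing, 256 ± 18.1 in Gansu, 455 ± 34.2 in Hubei and 111 ± 10.4 in Shanxi. Cinnamate 4-monooxygenase (C4H, TRINITY_DN18621_c0_g1_i3_4) stood at 55.9 ± 0.312, 223 ± 13.6, 592 ± 49.6 and 322 ± 24.3 CPM in the same order of areas, and 4-coumarate-CoA ligase 1 (4CL, TRINITY_DN22443_c1_g2_i2_2) at 56.8 ± 4.94, 159 ± 19.3, 356 ± 32.3 and 147 ± 8.9 CPM. Feruloyl-CoA ortho-hydroxylase (F6'H, TRINITY_DN22251_c0_g1_i3_3), which makes the coumarin ring, was at 16.6 ± 1.58 CPM in Chongqing, 610 ± 37.1 in Gansu, 352 ± 22.6 in Hubei and 254 ± 24.1 in Shanxi. Psoralen synthase (TRINITY_DN21601_c0_g3_i1_1), of furanocoumarin synthesis, was at 19.3 ± 1.29, 873 ± 76, 115 ± 11.2 and 140 ± 12.2 CPM. Bergaptol O-methyltransferase (TRINITY_DN22889_c3_g1_i9_1) was at 238 ± 12.3, 998 ± 103, 562 ± 46.7 and 618 ± 55 CPM. Umbelliferone 6-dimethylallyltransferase (TRINITY_DN22720_c1_g1_i16_4), which prenylates a simple coumarin, was at 67 ± 6.88 CPM in Chongqing and 64.7 ± 7.8 in Hubei against 431 ± 46.1 in Gansu and 211 ± 12.9 in Shanxi.

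Of the lignin branch, caffeoyl-CoA O-methyltransferase (CCoAOMT, TRINITY_DN14013_c0_g1_i2_2) and shikimate O-hydroxycinnamoyltransferase (HCT, TRINITY_DN23979_c0_g1_i4_3) were highest in Hubei, at 101 ± 11.8 and 455 ± 42.6 CPM, and lowest in Chongqing, at 13.1 ± 0.0387 and 28.9 ± 4.39 CPM. Of the terpenoid entry enzymes, 1-deoxy-D-xylulose-5-phosphate synthase 2 (DXS, TRINITY_DN17208_c0_g1_i1_3) was at 31.9 ± 1.61 CPM in Chongqing and 316 ± 31.1 in Shanxi, while 3-hydroxy-3-methylglutaryl coenzyme A reductase 1 (HMGR, TRINITY_DN14541_c0_g1_i1_3) stayed between 20.3 and 31.6 CPM in the 4 areas. Angelicin synthase (TRINITY_DN2443_c0_g2_i1_1), of the angular furanocoumarins, was low in every area, with a highest mean of 1.05 CPM in Gansu and 2 counts in the 3 Shanxi libraries.

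**Figure D2:**
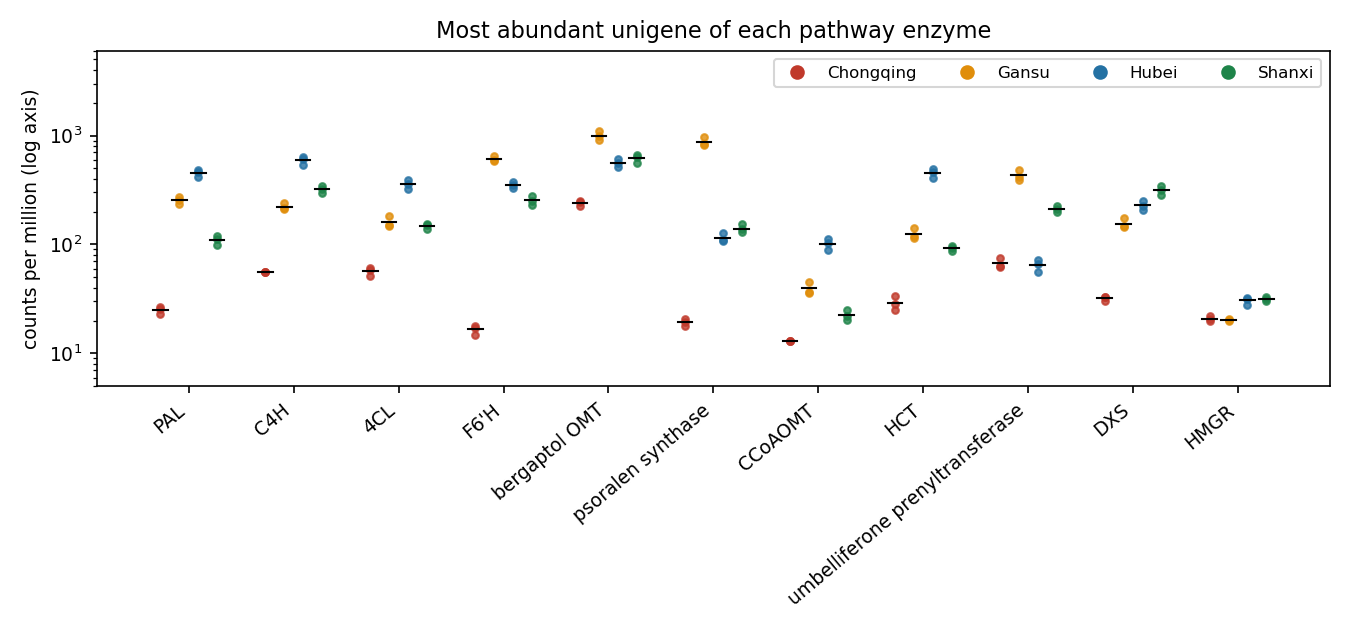
Points give the CPM of each of the 12 libraries on a log axis for the most abundant unigene of 11 pathway enzymes, coloured by area, and black lines give the mean of 3 libraries. PAL, C4H, 4CL, F6'H and psoralen synthase stand lowest in Chongqing, and psoralen synthase stands highest in Gansu at 873.

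Chongqing roots were lower than Hubei roots in the lists of cell wall remodelling and terpene synthases, calls of camera that held with an estimated correlation. Camera also called general phenylpropanoid and class III peroxidase unigenes lower and starch and sucrose unigenes higher, but these calls did not hold. The large subunit of glucose-1-phosphate adenylyltransferase (TRINITY_DN22886_c0_g1_i16_4), the committed enzyme of starch synthesis, was higher in Chongqing by a log2 fold change of 5.12 ± 0.09 (SE, 3 libraries per area), and sucrose synthase 3 (TRINITY_DN20225_c0_g1_i11_1) by 3.97 ± 0.07. PAL had a log2 fold change of -4.18 ± 0.10, F6'H of -4.41 ± 0.10, and peroxidase 42 (TRINITY_DN10457_c0_g1_i2_4) of -5.07 ± 0.09. Beta-bisabolene synthase (TRINITY_DN14865_c0_g1_i1_4), which makes a sesquiterpene, stood at 0.371 ± 0.285 CPM in Chongqing and 126 ± 4.88 in Hubei (-8.39 ± 0.19, or -9.18 without Chongqing replicate 1). In all, edgeR called 14366 unigenes higher and 15764 lower in Chongqing, 21351 of them by 2-fold or more, and 17380 summed proteins.

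Among unigenes with more than 3 counts in each area, the largest rise over Hubei was that of receptor-like protein 35 (TRINITY_DN18936_c0_g2_i1_1, 9.81 ± 0.43), a membrane protein of a family with roles in defense. Calcium-dependent protein kinase 17 (TRINITY_DN22142_c0_g2_i13_1, 9.45 ± 0.45), ABC transporter C family member 4 (TRINITY_DN20870_c0_g2_i6_2, 9.30 ± 0.39) and JOKA2 (TRINITY_DN18748_c0_g1_i2_1, 9.28 ± 0.37), an autophagy receptor, came next, but summed per protein their log2 fold changes were 3.46, 1.39 and 0.65. Without Hubei replicate 1 the first had 1 count in Hubei and a ratio of 4572 (95% counting interval 820 to 180595), and without Hubei replicate 3 its log2 fold change was 9.21. The kinase had 1 count there without Hubei replicate 3 and a ratio of 2104 (377 to 83145). The largest falls among such unigenes were those of linoleate 13S-lipoxygenase 2-1 (TRINITY_DN19578_c0_g1_i6_3, -9.66 ± 0.41, summed -2.01), initiation factor 4A-15 (TRINITY_DN21017_c0_g1_i8_2, -9.12 ± 0.45), HOS15 (TRINITY_DN23895_c1_g2_i3_4, -9.01 ± 0.31, summed -2.77) and cationic peroxidase 1 (TRINITY_DN7709_c0_g1_i1_3, -9.01 ± 0.30). Without Chongqing replicate 1 the lipoxygenase had 3 counts in Chongqing, a ratio of 1627 (95% counting interval 557 to 7892), and HOS15 had 2, a ratio of 899 (249 to 7427). The initiation factor then had 0 counts and was at least 645-fold lower, against a floor of 3 counts over the area.

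Of the 8 general phenylpropanoid unigenes, 8 were lower in Chongqing than in Hubei, also adjusted over the list alone (median log2 fold change -2.83, camera adjusted p = 5.1e-09; adjusted p = 0.12 with an estimated correlation). The coumarin list had 22 of 41 members lower and 8 higher, the same counts adjusted over the list alone (camera adjusted p = 0.003; adjusted p = 0.18 with an estimated correlation). Both F6'H and a second F6'H unigene (TRINITY_DN19624_c0_g1_i3_1, -3.61 ± 0.08) were among them. In the lignin list 48 of 92 members were lower and 24 higher, with 49 and 24 adjusted over the list alone (adjusted p = 0.00055; adjusted p = 0.32 with an estimated correlation). Laccase-14 (TRINITY_DN17321_c0_g1_i2_4) was at -6.19 ± 0.13 (summed -4.71). Of 44 prenyl diphosphate and terpene synthases, 27 were lower and 4 higher, also over the list alone, and this call (camera adjusted p = 3.3e-07) held (adjusted p = 0.035 with an estimated correlation). Myrcene synthase (TRINITY_DN18936_c0_g1_i1_3) was at -5.64 ± 0.13. Of 153 cytochromes P450, 82 were lower and 38 higher, with 85 and 39 adjusted over the list alone (adjusted p = 0.00057; adjusted p = 0.14 with an estimated correlation). P450 98A2 (TRINITY_DN19773_c1_g2_i4_2), an enzyme of caffeic acid derivatives, had a log2 fold change of -5.96 ± 0.11 and P450 81Q32 (TRINITY_DN20612_c0_g1_i3_3) of -3.72 ± 0.08.

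The cell wall remodelling list had 133 of 199 members lower in Chongqing and 32 higher, with 135 and 36 adjusted over the list alone, and its median was -2.23, or -2.14 with members at 0 counts set to their bound. This call held with an estimated correlation (4.3e-13 with the preset, adjusted p = 0.0078 with an estimated correlation). Extensin-2-like (TRINITY_DN19463_c0_g1_i11_2, -5.09 ± 0.09) and leucine-rich repeat extensin-like protein 5 (TRINITY_DN20459_c0_g1_i1_3, -4.86 ± 0.10), structural proteins of the wall, had the smallest p. Of 59 class III peroxidases, 42 were lower and 3 higher, with 42 and 4 adjusted over the list alone (adjusted p = 3.8e-13; adjusted p = 0.08 with an estimated correlation). Cationic peroxidase 1 (TRINITY_DN7984_c0_g1_i1_2) had a log2 fold change of -7.74 ± 0.15. In the xylem list 16 of 28 members were lower and 2 higher, also over the list alone (5.9e-05; adjusted p = 0.16 with an estimated correlation). Its leading members were fasciclin-like arabinogalactan proteins 2 (TRINITY_DN26520_c0_g1_i1_4, -3.21 ± 0.07) and 17 (TRINITY_DN23931_c0_g4_i1_3, -4.63 ± 0.16), wall glycoproteins that are not specific to xylem. Cell division had 103 of 228 members lower and 45 higher, with 104 and 48 adjusted over the list alone (0.013; adjusted p = 0.22 with an estimated correlation). Leading members were histone H2A unigenes (TRINITY_DN21923_c0_g6_i1_4, -7.17 ± 0.15, and TRINITY_DN16038_c0_g1_i1_4, -6.47 ± 0.21). The phloem list had 19 of 30 members lower and 5 higher, with 20 and 5 adjusted over the list alone (0.0067; adjusted p = 0.15 with an estimated correlation). PHLOEM PROTEIN 2-LIKE A1 (TRINITY_DN21634_c0_g1_i2_4, -1.92 ± 0.08) was among them.

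Jasmonate, ethylene and defense lists were called lower in Chongqing than in Hubei, without holding with an estimated correlation. Of 76 jasmonate unigenes 48 were lower and 10 higher, also over the list alone (camera adjusted p = 2e-06; adjusted p = 0.08 with an estimated correlation). Linoleate 13S-lipoxygenase 3-1 (TRINITY_DN18008_c0_g3_i1_2), an early enzyme of jasmonate synthesis, had a log2 fold change of -6.43 ± 0.12, and linoleate 9S-lipoxygenase 5 (TRINITY_DN13638_c0_g1_i1_2) one of -4.91 ± 0.08 (summed -2.03). Of 147 ethylene unigenes, 68 were lower and 39 higher, with 69 and 41 adjusted over the list alone (0.028; adjusted p = 0.45 with an estimated correlation). The list was led by 1-aminocyclopropane-1-carboxylate oxidase 1 (TRINITY_DN14571_c0_g1_i1_3, -5.76 ± 0.13), the last enzyme of ethylene synthesis. Of 473 defense unigenes, 199 were lower and 115 higher, with 205 and 119 adjusted over the list alone (0.042; adjusted p = 0.1 with an estimated correlation). MLP-like protein 34 (TRINITY_DN6107_c0_g1_i1_3) was at -5.42 ± 0.11. The phosphate starvation list had 28 of 55 members lower and 15 higher, with 28 and 17 adjusted over the list alone (0.044; adjusted p = 0.38 with an estimated correlation). A low affinity phosphate transporter (TRINITY_DN21999_c0_g2_i5_4) was at -7.15 ± 0.15. Of 130 starch and sucrose unigenes, 62 were higher and 36 lower, with 62 and 37 adjusted over the list alone (0.00071; adjusted p = 0.24 with an estimated correlation). The circadian clock list had 16 of 26 members higher and 7 lower, with 18 and 7 adjusted over the list alone (0.006; adjusted p = 0.37 with an estimated correlation). Adagio protein 3 (TRINITY_DN15635_c0_g1_i1_2), a light receptor of the clock, was at 2.24 ± 0.08. Of 193 transposable element unigenes, 75 were higher and 40 lower, with 76 and 40 adjusted over the list alone, and a median of 0.69, or 0.57 with members at their bound (0.029; adjusted p = 0.066 with an estimated correlation).

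**Figure D3:**
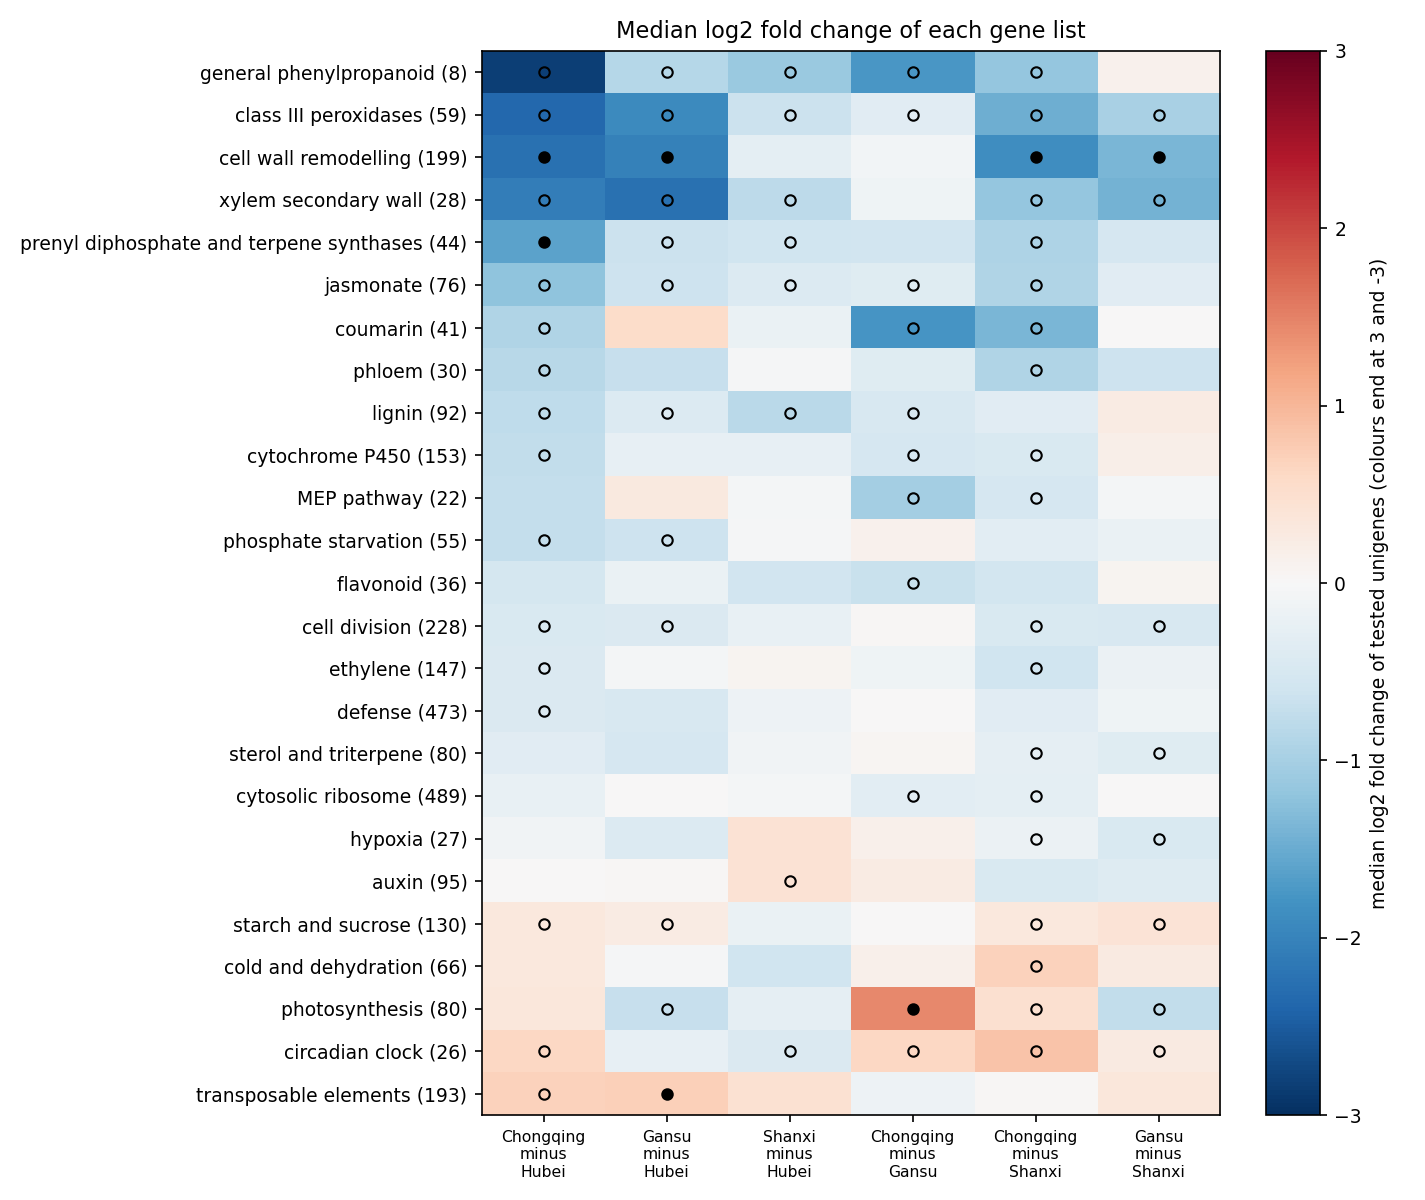
Colours give the median log2 fold change of the tested unigenes of each called list (number of unigenes in brackets) in the 6 pairs of areas. Circles mark camera calls, filled where the call held with an estimated correlation, as cell wall remodelling did in the 4 pairs that set Chongqing or Gansu against Hubei or Shanxi.

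Gansu roots were lower than Hubei roots in the cell wall remodelling list, a call that held with an estimated correlation. Camera also called class III peroxidase and photosynthesis unigenes lower and starch and sucrose unigenes higher, but these calls did not hold. The sugar transporter SWEET11 (TRINITY_DN20880_c0_g1_i5_3) stood at 396 ± 5.67 CPM in Gansu and 2.56 ± 0.229 in Hubei, a log2 fold change of 7.27 ± 0.19 (SE, 3 libraries per area), and sucrose synthase 3 was higher by 3.08 ± 0.07. Psoralen synthase was higher in Gansu by 2.92 ± 0.10 and the umbelliferone prenyltransferase by 2.74 ± 0.11 (summed 2.14), while PAL (-0.83 ± 0.09), C4H (-1.41 ± 0.08, summed -0.62) and HCT (-1.86 ± 0.11) were lower. Peroxidase 42 had a log2 fold change of -6.01 ± 0.09. Calls by edgeR numbered 14568 higher and 16130 lower in Gansu, 21728 of them by 2-fold or more, and 17313 summed proteins.

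Among unigenes with more than 3 counts in each area, the largest rises over Hubei were those of mitochondrial distribution and morphology protein 38 (TRINITY_DN12986_c1_g1_i1_4, 10.12 ± 0.40), organellar RNA editing factor 8 (TRINITY_DN7499_c0_g1_i1_3, 9.53 ± 0.23), thioredoxin-like 1-2 (TRINITY_DN21738_c0_g1_i6_1, 9.42 ± 0.25) and the histone methyltransferase ATX3 (TRINITY_DN22437_c0_g3_i1_4, 9.29 ± 0.22). Summed per protein, their log2 fold changes were 2.02, 0.84, 5.32 and 2.91. Without Hubei replicate 3 the first had 1 count in Hubei, a ratio of 3378 (95% counting interval 606 to 133463), and without Hubei replicate 2 thioredoxin-like 1-2 was at 10.13. The largest falls among such unigenes were those of kiwellin-1 (TRINITY_DN7145_c0_g1_i1_3, -9.88 ± 0.30), a defense-related secreted protein, EXORDIUM-like 2 (TRINITY_DN25828_c0_g1_i1_4, -9.35 ± 0.26) and endonuclease RE1 (TRINITY_DN23608_c0_g1_i9_2, -9.15 ± 0.21), a retrotransposon product. A unigene annotated as a bunyavirus glycoprotein was among them too, at -9.38 ± 0.33. Without Gansu replicate 2 kiwellin-1 had 3 counts in Gansu, a ratio of 1513 (517 to 7336), and without Gansu replicate 1 the glycoprotein had 1, a ratio of 2773 (497 to 109541). EXORDIUM-like 2 was at -8.71 without Gansu replicate 3.

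Cell wall remodelling was lower in Gansu than in Hubei for 125 of 199 members and higher for 37, with 127 and 37 adjusted over the list alone, and a median of -2.02, or -1.95 with members at their bound (camera adjusted p = 1e-11). This call held, at adjusted p = 0.0078 with an estimated correlation. Leucine-rich repeat extensin-like protein 5 was at -5.44 ± 0.10 and the polygalacturonase-1 subunit beta (TRINITY_DN16444_c0_g2_i1_2), of pectin breakdown, at -5.68 ± 0.13. Of 59 class III peroxidases, 38 were lower and 12 higher, also over the list alone (3.7e-07; adjusted p = 0.16 with an estimated correlation). Peroxidase 4 (TRINITY_DN18920_c0_g1_i1_2) was at -4.85 ± 0.12. The xylem list had 17 of 28 members lower and 4 higher, with 17 and 6 adjusted over the list alone (0.00027; adjusted p = 0.17 with an estimated correlation), again led by fasciclin-like arabinogalactan protein 2 (-3.88 ± 0.08). Of 228 cell division unigenes, 108 were lower and 42 higher, with 109 and 45 adjusted over the list alone (0.003; adjusted p = 0.16 with an estimated correlation). Among them were cyclin-B3-1 (TRINITY_DN22860_c1_g1_i1_1, -3.51 ± 0.10) and cyclin-D1-1 (TRINITY_DN22447_c0_g2_i1_3, -3.20 ± 0.10). Of 80 photosynthesis unigenes, 41 were lower and 8 higher, also over the list alone (0.00022; adjusted p = 0.066 with an estimated correlation). Oxygen-evolving enhancer protein 1 (TRINITY_DN30126_c0_g1_i1_2) was at -5.60 ± 0.15 and the Rubisco small subunit (TRINITY_DN21816_c0_g2_i3_4) at -2.60 ± 0.10.

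Of 130 starch and sucrose unigenes, 60 were higher in Gansu than in Hubei and 36 lower, with 61 and 36 adjusted over the list alone (camera adjusted p = 0.002; adjusted p = 0.27 with an estimated correlation). Of 193 transposable element unigenes, 80 were higher and 40 lower, with 84 and 40 adjusted over the list alone, and a median of 0.70, or 0.65 with members at their bound. This call (0.017) held, at adjusted p = 0.039 with an estimated correlation, but was lost with counts summed per protein (adjusted p = 0.12). Its Tf2-4 polyprotein (TRINITY_DN1113_c0_g1_i1_3) was at 9.02 ± 0.27, or 1.41 summed over 67 unigenes of the same protein. Of the 8 general phenylpropanoid unigenes 7 were lower, also over the list alone (0.0044; adjusted p = 0.34 with an estimated correlation). Of 92 lignin unigenes 49 were lower and 22 higher, with 50 and 22 adjusted over the list alone (0.033; adjusted p = 0.51 with an estimated correlation). Among them were caffeoylshikimate esterase (TRINITY_DN20946_c0_g6_i1_3, -3.48 ± 0.12) and dirigent protein 2 (TRINITY_DN19412_c0_g1_i2_3, -2.48 ± 0.09). Of 44 terpene synthases, 24 were lower and 8 higher, also over the list alone (0.00027; adjusted p = 0.1 with an estimated correlation). (R)-limonene synthase 1 (TRINITY_DN19951_c0_g1_i3_2) was at -5.32 ± 0.13. Of 76 jasmonate unigenes, 39 were lower and 18 higher, with 40 and 18 adjusted over the list alone (0.0089; adjusted p = 0.23 with an estimated correlation). TIFY 8 (TRINITY_DN18845_c0_g1_i2_2) was at -2.22 ± 0.08. The phosphate starvation list had 29 of 55 members lower and 18 higher, also over the list alone (0.033; adjusted p = 0.37 with an estimated correlation). Purple acid phosphatase 8 (TRINITY_DN22306_c0_g2_i3_4) was at -5.17 ± 0.18.

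Shanxi roots held high levels of transcripts annotated to viruses and, against Hubei roots, less PAL and more of the umbelliferone prenyltransferase. A unigene annotated as a nepovirus coat protein (TRINITY_DN22910_c0_g2_i1_3) stood at 17572 ± 773 CPM in Shanxi and 10.1 ± 7.85 in Hubei, a log2 fold change of 10.76 ± 1.62 (SE, 3 libraries per area), and one annotated as a viral polyprotein (TRINITY_DN22823_c0_g2_i2_4) at 15542 ± 1117 and 9.49 ± 8.21 (10.67 ± 1.51). PAL was at -2.04 ± 0.09 and HCT at -2.29 ± 0.11, while the umbelliferone prenyltransferase was higher by 1.70 ± 0.11. Bergaptol O-methyltransferase (0.14 ± 0.09, adjusted p = 0.25) and HMGR (0.04 ± 0.08, adjusted p = 0.74) did not pass the test. In this pair edgeR called 12782 unigenes higher and 14305 lower in Shanxi, 18722 of them by 2-fold or more, and 15692 summed proteins.

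Apart from the viral unigenes, the largest rises in Shanxi among unigenes with more than 3 counts in each area were those of a serine hydroxymethyltransferase (TRINITY_DN19136_c0_g2_i2_4, 10.90 ± 0.38, summed 2.24) and rhamnogalacturonan I rhamnosyltransferase 1 (TRINITY_DN23838_c0_g2_i4_4, 9.24 ± 0.62, summed 3.38), which builds pectin. The largest falls among such unigenes were those of linoleate 13S-lipoxygenase 2-1 (-10.44 ± 0.44, summed -3.85), miraculin (TRINITY_DN29504_c0_g1_i1_3, -10.39 ± 0.22), a protease inhibitor-like protein, endonuclease RE1 (-10.01 ± 0.23) and a regulatory subunit of protein phosphatase 2A (TRINITY_DN21779_c0_g1_i9_2, -9.78 ± 0.21). Several of these values rest on few counts in the lower area. Without Hubei replicate 3 the hydroxymethyltransferase had 2 counts in Hubei, a ratio of 3460 (95% counting interval 958 to 28573), and without Shanxi replicate 2 the lipoxygenase had 2 in Shanxi, a ratio of 2449 (678 to 20225). Without Shanxi replicate 1 miraculin had 1 count, a ratio of 4696 (843 to 185504), RE1 had 3, a ratio of 1883 (644 to 9134), and the phosphatase subunit was at -10.48.

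Fewer lists were called between Shanxi and Hubei, 8 of 33, and none of them held with an estimated correlation. Of the 8 general phenylpropanoid unigenes, 8 were lower in Shanxi, also adjusted over the list alone (camera adjusted p = 2.3e-06; adjusted p = 0.16 with an estimated correlation). A second C4H unigene (TRINITY_DN19642_c0_g1_i1_3) was at -4.65 ± 0.14, or -1.31 summed. Of 92 lignin unigenes, 49 were lower and 28 higher, with 50 and 28 adjusted over the list alone (0.019; adjusted p = 0.45 with an estimated correlation). Laccase-14 was at -2.62 ± 0.09. Of 44 terpene synthases, 18 were lower and 9 higher, with 20 and 9 adjusted over the list alone (0.047; adjusted p = 0.27 with an estimated correlation). Among them were (-)-germacrene D synthase (TRINITY_DN15158_c0_g1_i1_2, -8.74 ± 0.34) and farnesyl pyrophosphate synthase (TRINITY_DN24025_c0_g1_i3_4, -2.14 ± 0.09). Of 59 class III peroxidases, 30 were lower and 14 higher, with 31 and 17 adjusted over the list alone (0.0025; adjusted p = 0.31 with an estimated correlation). Leading members were peroxidase 73 (TRINITY_DN21134_c0_g1_i1_2, -4.35 ± 0.16) and peroxidase 12 (TRINITY_DN11983_c0_g1_i2_2, -2.55 ± 0.09). Of 76 jasmonate unigenes, 36 were lower and 24 higher, with 36 and 25 adjusted over the list alone (0.046; adjusted p = 0.33 with an estimated correlation). Linoleate 13S-lipoxygenase 3-1 was at -4.05 ± 0.10. The clock list had 14 of 26 members lower and 4 higher, with 16 and 4 adjusted over the list alone (0.0043; adjusted p = 0.34 with an estimated correlation). Among them were the pseudo-response regulators APRR7 (TRINITY_DN17238_c0_g1_i6_2, -1.23 ± 0.08) and APRR5 (TRINITY_DN20286_c0_g2_i1_1, -2.28 ± 0.14). The xylem list had 13 of 28 members lower and 4 higher, with 13 and 5 adjusted over the list alone (0.031; adjusted p = 0.34 with an estimated correlation). Fasciclin-like arabinogalactan protein 2 was at -1.85 ± 0.07. One list was higher in Shanxi, that of auxin, with 40 of 95 members higher and 21 lower, also over the list alone (0.039; adjusted p = 0.22 with an estimated correlation). Its SAUR20 (TRINITY_DN15956_c0_g2_i1_1) was at 8.96 ± 0.29, but had 1 count in Hubei without Hubei replicate 1, a ratio of 1488 (95% counting interval 267 to 58791), and SAUR32 (TRINITY_DN31641_c0_g1_i1_4) at 3.32 ± 0.14 but at -0.07 when summed.

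Chongqing and Gansu, the closest pair, were set apart by photosynthesis unigenes, higher in Chongqing, a call that held with an estimated correlation. Camera also called coumarin and flavonoid unigenes lower in Chongqing, but these calls did not hold. Psoralen synthase had a log2 fold change of -5.50 ± 0.11 (SE, 3 libraries per area) in Chongqing minus Gansu, F6'H of -5.20 ± 0.10 (summed -4.32), the umbelliferone prenyltransferase of -2.69 ± 0.11 and bergaptol O-methyltransferase of -2.07 ± 0.09. Chalcone synthase 2 was at -6.37 ± 0.13, while the unigene of chalcone synthase 1 (TRINITY_DN19794_c0_g1_i1_4) was higher in Chongqing by 9.16 ± 0.21. Without Gansu replicate 2 the latter had 2 counts in Gansu, a ratio of 1232 (95% counting interval 341 to 10179). The Rubisco small subunit stood at 963 ± 84 CPM in Chongqing and 73.1 ± 7.65 in Gansu (3.72 ± 0.10). The edgeR calls were 11778 higher and 11606 lower in Chongqing, 15547 of them by 2-fold or more, and 14146 summed proteins.

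Besides chalcone synthase 1, the largest rises over Gansu among unigenes with more than 3 counts in each area were those of calcium-transporting ATPase 1 (TRINITY_DN23383_c0_g1_i3_2, 9.61 ± 0.29, summed 2.21), ALA-interacting subunit 4 (TRINITY_DN21835_c0_g1_i18_2, 9.04 ± 0.43) and the kinesin KIN-14S (TRINITY_DN23626_c0_g2_i1_3, 8.99 ± 0.25, summed 2.96). Without Gansu replicate 1 the ATPase was at 10.86 and ALA-interacting subunit 4 had 1 count in Gansu, a ratio of 1925 (95% counting interval 345 to 76066), while it was at 8.38 without Gansu replicate 3. The largest falls among such unigenes were those of norbelladine synthase (TRINITY_DN21791_c0_g3_i2_1, -11.27 ± 0.29, summed -5.48), a replication protein A subunit (TRINITY_DN23765_c1_g3_i11_3, -10.60 ± 0.41, summed -1.70), ALWAYS EARLY 3 (TRINITY_DN23630_c0_g1_i5_3, -9.61 ± 0.22, summed -4.31) and organellar RNA editing factor 8 (-9.58 ± 0.23, summed -1.38). Without Chongqing replicate 1 norbelladine synthase had 2 counts in Chongqing, a ratio of 4463 (1235 to 36855), and the replication protein A subunit had 1, a ratio of 4571 (820 to 180583).

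The coumarin list had 23 of 41 members lower in Chongqing than in Gansu and 9 higher, with 24 and 9 adjusted over the list alone, and a median of -1.78, or -1.5 with members at their bound (camera adjusted p = 1.3e-06; adjusted p = 0.099 with an estimated correlation). Of the 8 general phenylpropanoid unigenes 7 were lower, also over the list alone (5.1e-09; adjusted p = 0.12 with an estimated correlation). PAL was at -3.35 ± 0.10. Of 80 photosynthesis unigenes, 47 were higher in Chongqing and 7 lower, with 49 and 8 adjusted over the list alone, and a median of 1.45, or 1.28 with members at their bound. That call held with an estimated correlation (9e-10 with the preset, adjusted p = 0.0078 with an estimated correlation). Of 36 flavonoid unigenes, 17 were lower and 5 higher, also over the list alone (0.0052; adjusted p = 0.17 with an estimated correlation). Of 92 lignin unigenes, 42 were lower and 22 higher, with 42 and 23 adjusted over the list alone (0.0064; adjusted p = 0.4 with an estimated correlation). Laccase-14 was at -7.48 ± 0.13 (summed -6.13). Of 153 cytochromes P450, 69 were lower and 31 higher, with 71 and 32 adjusted over the list alone (0.00071; adjusted p = 0.14 with an estimated correlation). CYP71D313 (TRINITY_DN23978_c0_g1_i1_4) was at -4.90 ± 0.07. The MEP pathway, the plastid route to terpenes, had 12 of 22 members lower and 6 higher, with 13 and 7 adjusted over the list alone (0.015; adjusted p = 0.27 with an estimated correlation). Its median was -1.01 and its mean 0.20, so that the mean differs in sign from the median and the test, and DXS was at -2.29 ± 0.10.

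Of 59 class III peroxidases, 25 were lower in Chongqing than in Gansu and 14 higher, with 25 and 15 adjusted over the list alone, and a median of -0.35, or -0.22 with members at their bound (camera adjusted p = 0.017; adjusted p = 0.4 with an estimated correlation). Peroxidase 45 (TRINITY_DN1232_c0_g1_i1_1, -6.41 ± 0.16) and a peroxidase 4 unigene (TRINITY_DN19554_c0_g1_i3_3, -3.34 ± 0.12) had the smallest p. Of 76 jasmonate unigenes, 30 were lower and 10 higher, with 32 and 12 adjusted over the list alone (0.0024; adjusted p = 0.17 with an estimated correlation). TIFY 10a (TRINITY_DN17597_c0_g1_i3_3), a repressor of jasmonate signalling, was at -4.90 ± 0.13. Of 26 clock unigenes, 17 were higher and 2 lower, also over the list alone (4.2e-05; adjusted p = 0.21 with an estimated correlation). Adagio protein 3 was at 1.13 ± 0.08 and APRR5 at 1.79 ± 0.13. Of 489 cytosolic ribosomal unigenes, 98 were lower and 27 higher, with 85 and 26 adjusted over the list alone (0.013; adjusted p = 0.65 with an estimated correlation). The 60S ribosomal protein L5 unigene (TRINITY_DN21811_c0_g1_i1_3) had 0 counts in Chongqing and was at least 411-fold lower there than in Gansu, against a floor of 3 counts over the area.

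Chongqing roots were lower than Shanxi roots in the cell wall remodelling list, a call that held with an estimated correlation. Ethylene and hypoxia unigenes were also called lower, and starch and sucrose, cold and dehydration and clock unigenes higher, but these calls did not hold. SWEET11 stood at 896 ± 21 CPM in Chongqing and 0.425 ± 0.433 in Shanxi, a log2 fold change of 11.03 ± 0.23 (SE, 3 libraries per area), and defensin-like protein 1 (TRINITY_DN8654_c0_g1_i1_1), an antifungal type of peptide, at 1449 ± 95.4 and 0.953 ± 0.862 CPM (10.57 ± 0.32). Without Shanxi replicate 3 these values were 12.28 and 11.61. F6'H was at -3.94 ± 0.10, psoralen synthase at -2.85 ± 0.10 and DXS at -3.31 ± 0.10. Fewer viral counts were present in Chongqing, with log2 fold changes of -11.44 ± 1.68 for the nepovirus coat protein and -11.67 ± 1.59 for the polyprotein. Both rest on Chongqing replicate 1, at 18.8 and 14 CPM. Without it the coat protein had 2 counts in Chongqing, a ratio of 401767 (95% counting interval 111220 to 3317523), and the polyprotein was at -16.84. Calls by edgeR numbered 13979 higher and 15051 lower in Chongqing, 20294 of them by 2-fold or more, and 16792 summed proteins.

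Receptor-like protein 35 (10.59 ± 0.46) and an IFF6-like cell wall protein (TRINITY_DN31865_c0_g1_i1_2, 10.17 ± 0.30) completed the largest rises over Shanxi among unigenes with more than 3 counts in each area. Without Shanxi replicate 3 the first had 0 counts in Shanxi and was at least 1522-fold higher in Chongqing, against a floor of 3 counts over the area, and without Shanxi replicate 1 the other had 2 counts, a ratio of 3637 (95% counting interval 1007 to 30035). A serine/threonine-protein kinase (TRINITY_DN24367_c0_g6_i2_3, -11.56 ± 0.37) and a G-type lectin receptor kinase (TRINITY_DN22824_c2_g1_i6_4, -9.87 ± 0.45, summed -0.88) completed the largest falls among such unigenes. Without Chongqing replicate 1 the former had 0 counts in Chongqing and was at least 2883-fold lower there, and the latter had 1 count, a ratio of 3316 (595 to 130999).

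Of 130 starch and sucrose unigenes, 58 were higher in Chongqing than in Shanxi and 30 lower, with 58 and 31 adjusted over the list alone (camera adjusted p = 2.7e-05; adjusted p = 0.17 with an estimated correlation). Glucose-1-phosphate adenylyltransferase was at 6.57 ± 0.10 and sucrose synthase 3 at 4.44 ± 0.07. Of 66 cold and dehydration unigenes, 35 were higher and 18 lower, with 35 and 19 adjusted over the list alone (0.0047; adjusted p = 0.37 with an estimated correlation). The list was led by the late embryogenesis abundant protein (7.88 ± 0.13) and the dehydrin (4.05 ± 0.08). Of 26 clock unigenes, 20 were higher and 4 lower, also over the list alone (1.4e-06; adjusted p = 0.16 with an estimated correlation). Adagio protein 3 was at 3.37 ± 0.09. Of 80 photosynthesis unigenes, 36 were higher and 15 lower, with 38 and 16 adjusted over the list alone (0.0082; adjusted p = 0.1 with an estimated correlation). Among them were the photosystem II 10 kDa polypeptide (TRINITY_DN4684_c0_g1_i1_1, 1.98 ± 0.08) and Rubisco small chain P8 (TRINITY_DN19621_c0_g1_i7_1, 4.79 ± 0.21, but -0.34 when summed).

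The cell wall remodelling list had 128 of 199 members lower in Chongqing than in Shanxi and 26 higher, with 132 and 28 adjusted over the list alone, and a median of -1.86, or -1.75 with members at their bound (camera adjusted p = 6.1e-13). This call held, at adjusted p = 0.0078 with an estimated correlation. A polygalacturonase (TRINITY_DN18606_c0_g1_i1_2) was at -5.31 ± 0.08. Of 59 peroxidases, 41 were lower and 6 higher, with 42 and 6 adjusted over the list alone (9e-10; adjusted p = 0.11 with an estimated correlation). Peroxidase 42 was at -4.74 ± 0.09. The xylem list had 17 of 28 members lower and 3 higher, with 18 and 3 adjusted over the list alone (0.00073; adjusted p = 0.2 with an estimated correlation). The list was led by fasciclin-like arabinogalactan proteins 1 (TRINITY_DN9433_c0_g1_i1_4, -2.30 ± 0.11) and 8 (TRINITY_DN14692_c0_g1_i1_2, -2.83 ± 0.14). The phloem list had 17 of 30 members lower and 3 higher, with 18 and 3 adjusted over the list alone (0.013; adjusted p = 0.16 with an estimated correlation). Of 228 cell division unigenes, 99 were lower and 51 higher, with 105 and 53 adjusted over the list alone (0.037; adjusted p = 0.27 with an estimated correlation). Of 147 ethylene unigenes, 75 were lower and 36 higher, with 75 and 38 adjusted over the list alone (0.00055; adjusted p = 0.27 with an estimated correlation). 1-aminocyclopropane-1-carboxylate oxidase 1 was at -7.28 ± 0.13 and ethylene-responsive transcription factor 13 (TRINITY_DN33413_c0_g1_i1_4) at -5.47 ± 0.10. Of 76 jasmonate unigenes, 39 were lower and 13 higher, also over the list alone (0.00029; adjusted p = 0.14 with an estimated correlation). 12-oxophytodienoate reductase 2 (TRINITY_DN22572_c0_g2_i1_4) was at -4.14 ± 0.17. The hypoxia list had 12 of 27 members lower and 6 higher, with 13 and 6 adjusted over the list alone (0.031; adjusted p = 0.42 with an estimated correlation). Among them were LOB domain-containing protein 41 (TRINITY_DN9538_c0_g1_i1_3, -2.68 ± 0.12) and pyruvate decarboxylase 4 (TRINITY_DN21842_c0_g2_i1_2, -1.90 ± 0.09), an enzyme of fermentation.

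In secondary metabolism, the general phenylpropanoid list had 6 of 8 members lower in Chongqing than in Shanxi and 1 higher, with 7 and 1 adjusted over the list alone (camera adjusted p = 0.0005; adjusted p = 0.27 with an estimated correlation). Of 41 coumarin unigenes, 24 were lower and 11 higher, also over the list alone (0.00041; adjusted p = 0.16 with an estimated correlation). Of 44 terpene synthases, 21 were lower and 10 higher, with 22 and 11 adjusted over the list alone (0.0053; adjusted p = 0.15 with an estimated correlation). Beta-bisabolene synthase was at -9.53 ± 0.19, or -10.34 without Chongqing replicate 1. The MEP pathway had 12 of 22 members lower and 3 higher, also over the list alone (0.033; adjusted p = 0.32 with an estimated correlation). Of 153 cytochromes P450, 74 were lower and 39 higher, with 76 and 42 adjusted over the list alone (0.0096; adjusted p = 0.18 with an estimated correlation). Of 80 sterol and triterpene unigenes, 35 were lower and 17 higher, with 36 and 19 adjusted over the list alone (0.031; adjusted p = 0.27 with an estimated correlation). Leading members were oxysterol-binding protein-related protein 2A (TRINITY_DN21333_c0_g1_i3_2, -5.69 ± 0.14, summed -2.26) and sterol esterase TGL1 (TRINITY_DN24300_c1_g1_i3_3), which releases sterols from their esters. Of 489 cytosolic ribosomal unigenes, 186 were lower and 42 higher, also over the list alone (0.006; adjusted p = 0.6 with an estimated correlation). 40S protein S23 (TRINITY_DN18343_c0_g1_i2_3) was at -6.33 ± 0.29 (-6.92 without Chongqing replicate 1) and 60S protein L5 at least 408-fold lower in Chongqing, where it had 0 counts.

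Gansu roots were lower than Shanxi roots in the cell wall remodelling list as well, a call that held with an estimated correlation. Camera also called hypoxia unigenes lower and starch and sucrose unigenes higher, but these calls did not hold. The coumarin list was not called (camera adjusted p = 0.5). SWEET11 was higher in Gansu by a log2 fold change of 9.85 ± 0.23 (SE, 3 libraries per area; 11.10 without Shanxi replicate 3), glucose-1-phosphate adenylyltransferase by 4.43 ± 0.09 and sucrose synthase 3 by 3.55 ± 0.07. Psoralen synthase was higher by 2.64 ± 0.09, F6'H by 1.27 ± 0.09 (summed 0.63) and PAL by 1.21 ± 0.09. For C4H the unigene was at -0.53 ± 0.08 and the summed protein at 0.68, and 4CL (0.11 ± 0.10, adjusted p = 0.38) did not pass the test. The edgeR calls were 12881 higher and 13926 lower in Gansu, 18053 of them by 2-fold or more, and 16116 summed proteins.

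The largest rises over Shanxi among unigenes with more than 3 counts in each area, beside SWEET11, were those of vacuolar-sorting receptor 6 (TRINITY_DN22735_c1_g3_i3_2, 10.06 ± 0.13), the RNA-binding protein RZ1C (TRINITY_DN18080_c0_g1_i2_2, 9.80 ± 0.30, but 0.00 when summed) and early light-induced protein 1 (TRINITY_DN9936_c0_g1_i2_3, 9.62 ± 0.20). Without Shanxi replicate 1 RZ1C had 0 counts in Shanxi and was at least 1095-fold higher in Gansu, against a floor of 3 counts over the area. The viral polyprotein (-10.74 ± 1.52) and coat protein (-10.54 ± 1.61), the serine hydroxymethyltransferase (-10.04 ± 0.36, summed -1.67) and DRT100 (TRINITY_DN14917_c0_g1_i1_4, -9.60 ± 0.21), a leucine-rich repeat protein, fell most among such unigenes. The values of the coat protein, the polyprotein and the hydroxymethyltransferase rest on Gansu replicate 3, at 33.9, 25.7 and 0.37 CPM. Without it the coat protein and the hydroxymethyltransferase had 0 counts in Gansu and were at least 232531-fold and 2012-fold lower there. The polyprotein then had 3 counts, a ratio of 205551 (95% counting interval 70335 to 996736).

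Cell wall remodelling had 118 of 199 members lower in Gansu than in Shanxi and 26 higher, with 122 and 28 adjusted over the list alone, and a median of -1.36, or -1.27 with members at their bound (camera adjusted p = 3.4e-11). This call held, at adjusted p = 0.0078 with an estimated correlation. The polygalacturonase unigene was at -5.41 ± 0.09 and polygalacturonase At1g48100 (TRINITY_DN19488_c0_g1_i1_4) at -6.69 ± 0.14 (summed -6.08). Of 59 peroxidases, 33 were lower and 13 higher, also over the list alone (0.0013; adjusted p = 0.31 with an estimated correlation). Peroxidase 42 was at -5.68 ± 0.09. The xylem list had 16 of 28 members lower and 4 higher, also over the list alone (0.0005; adjusted p = 0.18 with an estimated correlation). The list was led by fasciclin-like arabinogalactan proteins 2 and 1 (-2.03 ± 0.08 and -2.90 ± 0.12). Of 228 cell division unigenes, 98 were lower and 36 higher, with 100 and 37 adjusted over the list alone (0.0055; adjusted p = 0.17 with an estimated correlation). Cyclin-D1-1 was at -2.88 ± 0.10. Of 80 photosynthesis unigenes, 36 were lower and 12 higher, with 37 and 12 adjusted over the list alone (0.0013; adjusted p = 0.08 with an estimated correlation). Photosystem I chlorophyll-binding protein 3-1 (TRINITY_DN15494_c0_g1_i2_3) was at -3.12 ± 0.11. The hypoxia list had 13 of 27 members lower and 2 higher, also over the list alone (0.0069; adjusted p = 0.33 with an estimated correlation). Among them were pyruvate decarboxylase 1 (TRINITY_DN21842_c0_g1_i1_2, -2.51 ± 0.08) and non-symbiotic hemoglobin 1 (TRINITY_DN24597_c1_g1_i4_4, -8.29 ± 0.41, or -8.92 without Gansu replicate 1, summed -3.94), an oxygen-binding protein. Of 80 sterol and triterpene unigenes, 37 were lower and 16 higher, with 38 and 16 adjusted over the list alone (0.011; adjusted p = 0.21 with an estimated correlation). The sterol transporter NPC1-related protein 1 (TRINITY_DN17832_c0_g1_i3_3) was at -2.55 ± 0.06. Of 130 starch and sucrose unigenes, 63 were higher and 30 lower, with 67 and 33 adjusted over the list alone (3.2e-05; adjusted p = 0.17 with an estimated correlation). Of 26 clock unigenes, 12 were higher and 6 lower, with 13 and 6 adjusted over the list alone (0.022; adjusted p = 0.45 with an estimated correlation). Adagio protein 3 was at 2.24 ± 0.09.

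Over the 6 pairs, camera called 76 of 198 combinations of list and pair, and 7 of these calls held with an estimated correlation, 4 of them for cell wall remodelling and 1 each for terpene synthases, photosynthesis and transposable elements. With counts summed per protein camera called 56 combinations and 23 of the 76 calls were lost, that of transposable elements between Gansu and Hubei among them. Of the 33 lists, 8 were called in no pair, and their smallest camera adjusted p were 0.066 for metal homeostasis, 0.15 for UDP-glycosyltransferases, 0.16 for the mevalonate pathway, 0.17 for abscisic acid, 0.18 for nitrogen supply, 0.19 for antioxidant enzymes, 0.28 for gibberellin and flowering and 0.32 for heat shock. The list of plant virus terms had 2 members and was not tested as a list.

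Transcripts annotated to other viruses and to a mould were present as well. Beside the nepovirus and polyprotein unigenes of Shanxi, the bunyavirus glycoprotein unigene (TRINITY_DN5779_c0_g1_i1_2) stood at 63.9 ± 3.92 CPM in Hubei (mean ± SD, n = 3, over the deposited total without TMM scaling) and at 0.0292 to 0.217 in the other areas. A unigene annotated as the polymerase of a negative-strand virus stood at 18.7 ± 1.01 in Chongqing and 23.7 ± 1.27 in Hubei, at 0.101 in Gansu, and had 0 counts in the 3 Shanxi libraries, which allows up to 0.129 to 0.131 CPM in each. The 522 unigenes annotated to the mould Rhizopus summed to 1492 ± 301 CPM in Chongqing, 2077 ± 533 in Gansu, 3145 ± 854 in Shanxi and 1055 ± 24.8 in Hubei. This sum was not tested between areas, and the libraries of Gansu (1728 to 2690) overlapped with those of Chongqing (1157 to 1738) and of Shanxi (2582 to 4128). Without the 662 unigenes of fungal or viral annotation, chosen after the data were seen, every count of calls stayed within 1.5 times its value. Counts could hardly move, as 60390 of 60756 tested unigenes stayed, so effects on plant unigenes were not tested.

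**Figure D4:**
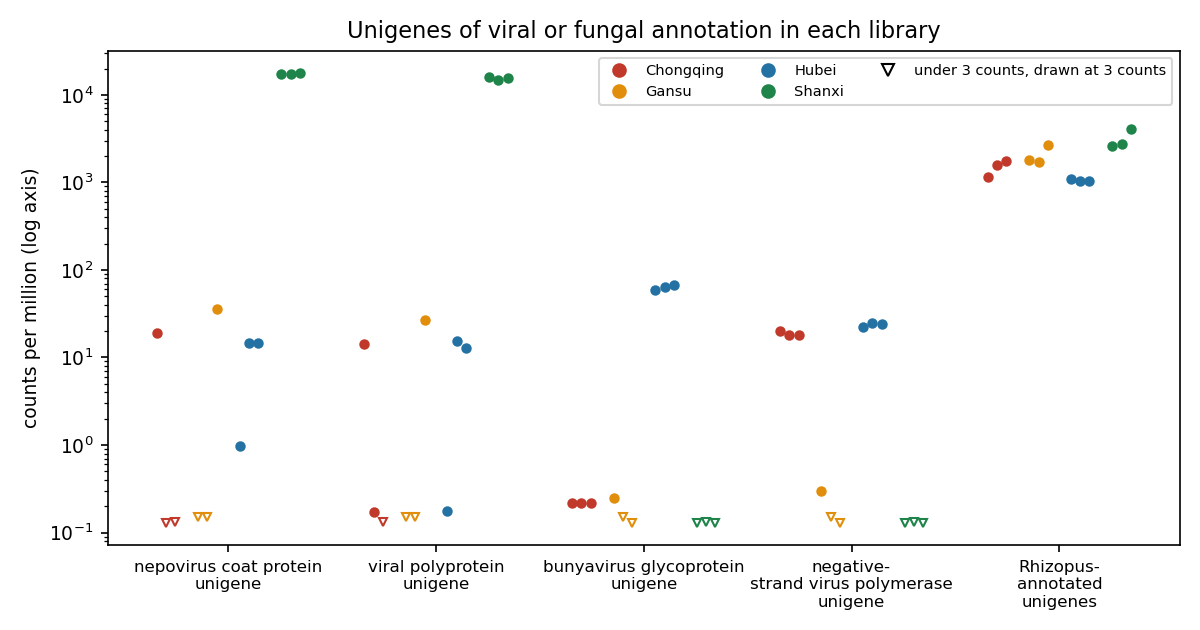
Points give the CPM over the deposited total of viral and Rhizopus-annotated unigenes in each of the 12 libraries on a log axis, coloured by area, and open triangles mark libraries under 3 counts, drawn at the level of 3 counts. The 3 Shanxi libraries hold 14792 to 17675 for both nepovirus-type unigenes, and single libraries of the other areas hold traces of 12.8 to 35.5.

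Unigenes detected in 1 area only, with 10 or more counts in each of its 3 libraries and 0 in the 9 others, numbered 323 in Chongqing, 344 in Gansu, 284 in Hubei and 345 in Shanxi, 1296 in all. The other 216 sets of 3 libraries held at most 1 such unigene, and no other of the 15400 partitions of the libraries reached the total (exact permutation, one-sided p = 6.5e-05, the smallest possible, highest other partition 690). Their median level in the area that held them was 1.42 to 1.70 CPM. A best protein was known for 108, 140, 109 and 129 of them in the same order of areas, and 51.2% to 58.3% of these matched a protein that another, more widely detected unigene matched as well.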

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

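Of the tests in this part, the comparison of the ratio of viral unigenes was chosen only after the result was seen, and the carry-over test was set before its result was known. The signals come from unigenes annotated to viruses or a mould, without a test of whether they are sequences of the plant itself, and are set against the limit of a count of 0, since no library serves as a control. Levels are CPM over the deposited total. The nepovirus coat protein unigene reached 17675 in Shanxi replicate 3 and the viral polyprotein unigene 15878 in Shanxi replicate 1. The bunyavirus glycoprotein unigene reached 67.6 in Hubei replicate 3 and the negative-strand virus polymerase unigene 24.5 in Hubei replicate 2. Unigenes annotated to Rhizopus summed to 4128 in Shanxi replicate 3, the highest library. Unigenes annotated to a paramyxovirus reached 5.67 in Chongqing replicate 1, with 87 to 131 counts in 8 libraries and 0 or 1 in Gansu replicate 3, Shanxi replicate 1, Hubei replicate 1 and Hubei replicate 2, a split that crosses the areas. The nepovirus-type unigenes were high in the 3 Shanxi libraries and left traces of at least 20 counts each in Chongqing replicate 1, Gansu replicate 3, Hubei replicate 2 and Hubei replicate 3.

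General carry-over of Shanxi RNA or reads would bring other Shanxi transcripts at the rate of the virus, and 45 unigenes that were high in Shanxi and at 0 in the other 2 Gansu libraries held 89 counts (95% Poisson interval 71.5 to 110) in Gansu replicate 3, where 79.4 were expected. Gansu replicate 3 thus held the counts expected of carry-over, against 1 and 0 in the other Gansu libraries over fewer unigenes. For Chongqing and Hubei the test is less clear, since Chongqing replicate 1 (180 counts), Hubei replicate 2 (59) and Hubei replicate 3 (48) held more than the 53.6, 21.8 and 22 expected, and so did libraries nearly free of the virus, Chongqing replicate 2 (23 against 0.178), Chongqing replicate 3 (13 against 0.0946) and Hubei replicate 1 (20 against 0.536), which may express some of these unigenes. Carry-over would keep the Shanxi ratio of the viral unigenes, 1.1 to 1.17. Gansu replicate 3 was at 1.32 (1.19 to 1.47, counting error only). Shanxi libraries differed beyond such error (1.09 to 1.1 and 1.16 to 1.17), so the ratio leaves the Gansu trace undecided. The intervals of the other 3 traces reached that range and cannot tell the Shanxi virus from a separate low infection. An infection of the Shanxi plants as such stays open and was not tested.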

How the results depend on the processing

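The settings with summed proteins, the paramyxovirus covariate, no fungal or viral unigenes, only unigenes with counts in every library, and the count of unigenes of 1 area without each library were chosen after the result was seen, and the others before. Across all settings, named unigenes kept direction and side of the threshold in 6578 comparisons, became weaker in 33, stronger in 7 and reversed in 4; list tests did so in 3464, 173, 124 and 1. Of 255 called fold changes of named unigenes, 39 moved by over 1.5 times without 1 library and kept their call, and 2 lost it, that of angelicin synthase and that of psoralen synthase in Shanxi minus Hubei (0.28, and 0.22, 0.25 and 0.23 without Shanxi replicate 1, Hubei replicate 2 and Hubei replicate 3). Without each library in turn the calls ran from 42069 to 43937 for any difference, 27554 to 31409 for Chongqing and Hubei, 28430 to 31133 for Gansu and Hubei, 24682 to 28372 for Shanxi and Hubei, 21014 to 23837 for Chongqing and Gansu, 26700 to 30377 for Chongqing and Shanxi, and 24534 to 27345 for Gansu and Shanxi, with 70 to 77 list calls, a distance of 0.212 to 0.217 and 1356 to 1418 unigenes of 1 area. Summing per protein tests fewer features and gave 22108 calls for any difference and 17380, 17313, 15692, 14146, 16792 and 16116 for the pairs in that order. A 2-fold minimum, stricter by construction, gave 15547 for Chongqing and Gansu. List calls fell to 7 with an estimated correlation and were 172 with fry, which does not compare a list with other genes. Unigenes of 1 area numbered 282 with at least 50 counts and 2092 with up to 2 counts elsewhere, against 1296. The other settings moved counts by less than 1.5 times. The distance between minus within areas ran from 0.118 to 0.217, lowest with counts summed per protein and highest as 1 minus Pearson's correlation of log2(FPKM + 1), and p was 6.5e-05 under each. Summing reversed TRINITY_DN22720_c1_g1_i16_4 in Chongqing minus Hubei (-0.35), TRINITY_DN31641_c0_g1_i1_4 in Shanxi minus Hubei (-0.07), TRINITY_DN19621_c0_g1_i7_1 in Chongqing minus Shanxi (-0.34) and TRINITY_DN18621_c0_g1_i3_4 in Gansu minus Shanxi (0.68), and fry the nitrogen supply list in Gansu minus Shanxi (adjusted p = 0.029); the cause was not tested. With the replicate block the calls were 41308 for any difference and 28867, 29449, 25793, 22202, 27769 and 25590 for the pairs, with 69 list calls. The replicate numbers did not pair the libraries: 18 same-number pairs correlated at -0.33 to 0.31, 5 of them above 0.1, and 5 of 12 libraries correlated best with their own number. No scaling moved the median fold change of all unigenes by over 0.1. Depth limits what can be detected to about 3 counts in a library. The call of angelicin synthase (TRINITY_DN2443_c0_g2_i1_1) in Chongqing minus Gansu was lost when any 1 of 11 libraries was left out. In simulated counts for Chongqing against Hubei, where few unigenes were changed, 24% of changes of 1.5-fold were recovered. Whether depth, the spread between libraries or their number limits either was not tested.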

Other observations

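The tests of assembly splitting, of the paramyxovirus split, of time of day and of dormancy in Chongqing against Shanxi alone were chosen only after the result was seen, while the dormancy test over the 4 pairs and the regrouping of libraries were set before. Across areas, the 4 pairs that set Chongqing or Gansu against Hubei or Shanxi shared a direction for several groups. By camera, starch and sucrose unigenes were higher in Chongqing and Gansu in these 4 pairs, and cell wall remodelling, class III peroxidase, xylem and cell division unigenes lower, of which cell wall remodelling alone held with an estimated correlation. Jasmonate unigenes were called lower in 3 of the 4, the exception being Gansu and Shanxi (camera adjusted p = 0.29). These pairs share libraries, so the shared directions are not independent. The last number of the unigene identifiers went with the area. Of tested unigenes ending in 1, 51.1% had their highest level in Chongqing, of those ending in 2 and in 3, 53.1% and 33.8% in Hubei, and of those ending in 4, 43.3% in Shanxi. Among unigenes of 1 area, 84.2% of those of Chongqing ended in 1, 78.9% of those of Hubei in 2, and 50% of those of Gansu and 84.9% of those of Shanxi in 4. In the same set 0% of those of Chongqing ended in 3 or 4, of Gansu in 2, of Hubei in 1 or 4, and of Shanxi in 1 or 2. What the number marks is not given in the labels, and its bearing on the unigenes of 1 area was not tested.

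Most unigenes differed between areas, and of 100 partitions of the 12 libraries only the real one (1) gave as many calls (42773 against a highest other of 4909). This argues against a random grouping of these libraries, although mixing areas within a group also raises the spread and lowers the calls. Since the replicates may be technical, regrouping cannot tell a difference between areas from one between single plants or pools. Assembly of 1 gene as several unigenes that each follow 1 area may add to the calls, since 7.33% to 10.7% of proteins with several unigenes had members that moved in opposite directions by 2-fold or more, but 22.6% to 32.3% of such proteins still differed by 2-fold or more in each pair when summed, which argues against it as the whole cause. It stays open for part of the calls, since only 43.9% to 51.5% of those with a called unigene of 2-fold or more kept such a change when summed, and unigenes of 1 gene can also match different proteins. A sequencing or library split marked by paramyxovirus reads is argued against as well, since 41190 unigenes were still called with it as a covariate, and differences in genotype or environment between the areas stay open, untested. For the 6 pairs the 10 splits of 6 libraries are too few for a share under 0.05. Real values were 23384 to 30698 calls and the highest other 0 by edgeR, where 867 to 3337 unigenes had an unadjusted p under 0.05 in the other splits.

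For gene lists, 1 of 40 partitions, the real one, gave as many calls (76 against a highest other of 67). So few partitions and so narrow a margin do not exclude chance for their number. The high count in other partitions shows that list calls at the preset correlation also arise where libraries of an area are mixed.

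As a hypothesis for the direction shared by Chongqing and Gansu, roots nearer dormancy at harvest would hold more transcripts of dormancy-associated and auxin-repressed proteins. The median log2 fold change of these 9 unigenes was -0.55 instead, with 2 higher and 7 lower, and lay below 0 in 3 of the 4 pairs. Between Chongqing and Shanxi it was 0.43, with 6 higher and 3 lower. The prediction thus failed for the direction that the 4 pairs share, but 9 unigenes alone cannot decide. Other signs of dormancy were not weighed, so the explanation stays open. A different time of day at harvest would move dawn and dusk clock unigenes in opposite directions, and the medians were 0.40 for 8 dawn unigenes and 0.74 for 13 dusk unigenes. Time of day may still differ and cannot be told apart from other causes, since the dusk median was -0.11 between Gansu and Hubei and the harvest hour was not used here. Climate, soil and genotype of the areas stay open and were not tested.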
